A study of Rattus norvegicus with 9 samples.

How the data were processed

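Gene expression in rat ventral midbrain was measured on 9 Affymetrix rat expression arrays: 3 with RNA from tissue of embryonic day 11 (MesE11) and 6 with RNA from primary cultures grown from such tissue for 9 days (MesPC). Per the labels' protocols, total RNA was isolated with Tri-Reagent and labelled with biotin by the standard Affymetrix protocol. The authors made the deposited values with RMA, per the submitters' processing notes, whose version is not given in the sources used here. RMA corrects the background of the probes, normalizes the arrays to each other and summarises each probe set. The deposited values are log2 intensities: they ran from about 4.7 to 14.8, and the array medians lay between 8.61 and 8.67. The scanner files were not used here, so the probe-level steps were taken as the authors made them. Because RMA fits the arrays to nearly the same distribution, every difference is relative to the other probe sets on the same array. The fit was not exact: the lower quartile was 7.15 to 7.21 in tissue arrays and 6.98 to 7.11 in culture arrays. Dim probe sets thus read slightly lower in culture as a whole, and small falls of dim genes may hold this shift. Under quantile normalization Pax8, Des, Myh3, Rax, Ifit3 and Bdnf lost their calls.

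The table held 15923 probe sets. The 57 Affymetrix control probe sets were left out of the tests, and 15866 were tested. Gene symbols came from the probe annotation of the array, which listed 13095 of the probe sets, 12783 of them with 1 symbol and 312 with several; 2771 were not listed. The Entrez gene numbers of 12754 were found in a RefSeq gene table of the assembly GRCr8, which changed 0 symbols and was used for names alone; no genome coordinates are given. The probe sets with 1 symbol stood for 10411 genes. For the 1868 genes with several probe sets, the one with the highest mean over the 9 arrays was used; 45 genes had probe sets called in opposite directions.

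The 6 culture arrays were compared with the 3 tissue arrays, the only contrast that the labels give. limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings) gave each probe set a log2 difference, its moderated standard error and a two-sided p, adjusted over all tested probe sets by the Benjamini-Hochberg method with a threshold of 0.05. Counts at 2-fold or more used the same fit. Gene groups were tested with limma's camera over 1 probe set per gene, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and limma's fry stood beside it. The number of arrays limits the power of camera with an estimated correlation. Members of each list were also adjusted over the list alone. Pearson correlations between arrays and principal components described the spread and were not tested. Plots were drawn with matplotlib 3.10.9.

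The tests, the 23 gene lists and the rule for the genes named in the text were fixed before the data were examined. The lists were midbrain patterning and floor plate, dopaminergic neuron, cell cycle, neural progenitor, neuronal cytoskeleton and RNA-binding, synaptic vesicle and synapse, voltage-gated ion channel, GABA and glutamate transmission, serotonergic and cholinergic neuron, neuropeptide and neurotrophin, astrocyte, oligodendrocyte lineage, microglia and macrophage, fibroblast and smooth muscle, endothelium, erythroid, embryonic skeletal muscle, forebrain identity, hindbrain and spinal Hox, cholesterol synthesis, interferon and MHC class I, stress and immediate early, and cytosolic ribosomal protein. The rule took the 10 genes with the largest rise and the 10 with the largest fall past the threshold whose 6 culture values all lay on one side of the 3 tissue values, leaving out predicted loci. From each list it took up to 4 such members in the direction that most of its called members took and up to 2 in the other. It always took Th, Slc6a3, Slc18a2, Ddc, Nr4a2, Pitx3, Lmx1a, Lmx1b, Foxa2, En1, En2, Wnt1, Shh, Neurog2, Tph2, Gfap, Olig2 and Bdnf, and a further gene that is not reported here. Of these, Lmx1a, Lmx1b, En1, En2, Wnt1, Neurog2, Tph2 and Olig2 had no probe set with that symbol alone and were not analysed here. Other genes named were chosen after their values were seen and are said to be so.

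The fit was tested on simulated arrays with the spread of the real probe sets and 200 planted changes among 15866 probe sets. It recovered 50 of 67 changes of 0.5 log2 units (74.6%), 65 of 67 of 1 unit (97.0%) and 66 of 66 of 2 units; 17 of its 198 calls were false. Camera called the shifted list and 0 of 20 unshifted ones. The simulated probe sets were drawn independently of each other and without sets of like culture arrays. Real lists had estimated correlations of up to 0.88, so the simulation cannot judge the preset correlation.

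The alternatives planned were quantile normalization again, centring on the median of all probe sets or of ribosomal protein probe sets, leaving out the dimmest 40% or 60% of probe sets, a trended and robust variance, array weights, leaving out each array in turn, the replicate number as a block, every choice of 3 culture arrays, every way to average the culture arrays in pairs, limma's treat, the mean of a gene's probe sets, and both other set tests. Added after the data were seen were a random block for sets of culture arrays, fitted with duplicateCorrelation and statmod 1.5.0, each set alone, and the estimated correlation in each set. In the random block the 3 tissue arrays formed a set of their own, so they were treated as correlated too. The block applied 1 correlation to every probe set and still counted arrays as samples. It is therefore not a test with the sets as samples, and p stays too small for genes whose culture sets differ more than that correlation allows. The labels speak of cultures made in duplicate without saying which arrays are duplicates, and of 3 culture samples where 6 arrays are present. All 6 were therefore treated as separate samples, and the number of independent cultures stayed unknown. The labels give 3 embryo groups, so the cultures may stem from no more than 3 independent pools, shared with the tissue. The main fit was unpaired and ignored such a shared origin. All deposited sample columns were used. For arrays there is no count depth; their number limits the precision.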

Results

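Expression was measured in the ventral midbrain of rat embryos and in cultures grown from it. Per the labels, embryos of embryonic day 11 from 4 pregnant rats were mixed into 3 groups, and the ventral midbrain of each group was taken as a tissue pool (MesE11, 3 arrays) or dissociated and grown in vitro for 9 days (MesPC, 6 arrays). The ventral midbrain is where midbrain dopaminergic neurons arise. The title of the series sets the question: how the expression profile of primary neuronal cultures compares with that of the embryonic mesencephalon. Values are log2 intensities, differences are MesPC minus MesE11, and each is given ± its standard error from 3 and 6 arrays unless stated otherwise. The number of arrays limits the precision.

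The tissue arrays were alike, while the culture arrays fell into separate sets. Across probe sets, which are not independent replicates, Pearson's r was 0.995 to 0.997 between tissue arrays. The culture arrays formed a set numbered 1 to 3 and a set numbered 4 to 6: r was 0.997 to 0.998 within either set and 0.982 to 0.987 between them. Culture arrays 4 to 6 were nearer to tissue, with r of 0.966 to 0.974 against 0.943 to 0.953 for arrays 1 to 3. The labels name nothing that parts these sets. The median standard deviation of a probe set was 0.0916 in tissue and 0.115 in culture. The difference between the hybridization controls BioD and BioB was 2.42 to 2.46 in tissue and 2.73 to 3.14 in culture, without overlap. The 3′ minus 5′ differences of the GAPDH (0.705 to 0.775 in tissue, 0.558 to 0.729 in culture) and actin controls (0.515 to 0.798 and 0.350 to 0.669) overlapped. However, 5 of 6 culture arrays lay below every tissue array for GAPDH, all but MesPC replicate 4, and 3 of 6 for actin, arrays 1 to 3.

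**Figure D1:**
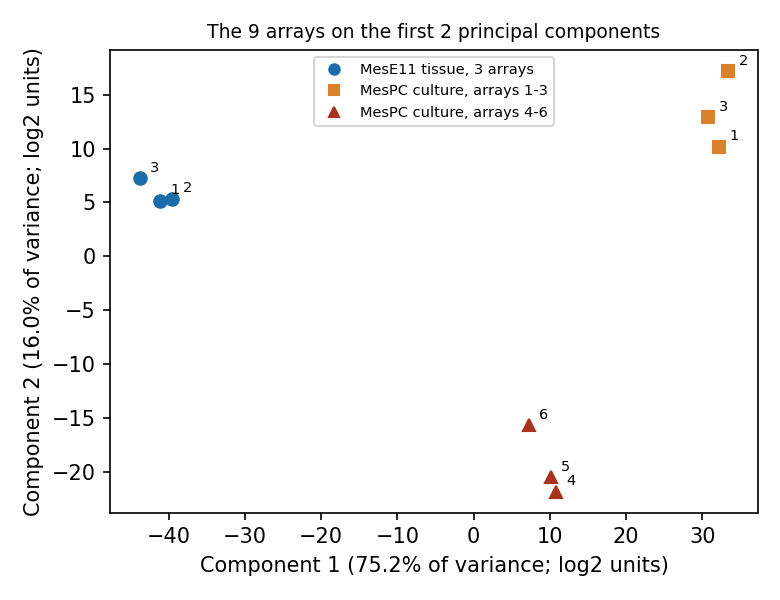
Principal components of the 9 arrays, with 1 point per array and the share of variance on each axis. The first component (75.2%) parts the 3 tissue arrays (−43.8 to −39.6) from the 6 culture arrays. It also parts culture arrays 1 to 3 (30.8 to 33.4) from arrays 4 to 6 (7.3 to 10.8), which lie nearer to tissue. The second (16.0%) stretches between culture arrays 1 to 3 and 4 to 6.

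In culture, 16 of 21 fibroblast and smooth muscle genes, 19 of 23 cell cycle genes and 10 of 16 astrocyte genes were higher than in embryonic midbrain. Lower were 12 of 15 dopaminergic, 8 of 17 neuronal cytoskeleton, 14 of 25 synaptic, 9 of 10 erythroid, 7 of 10 endothelium and 10 of 18 microglia genes. With a random block for the 2 sets of culture arrays and the tissue arrays these counts were 15, 13 and 8 higher and 8, 6, 9, 6, 7 and 6 lower. Camera called these lists with its preset correlation, but none of the 23 lists with an estimated one (lowest adjusted p = 0.0756 with an estimated correlation). Col3a1, the chain of type III collagen, rose from 7.51 to 13.07, by 5.56 ± 0.13 or 47.1-fold. Th, tyrosine hydroxylase, the rate-limiting enzyme of dopamine synthesis, fell from 11.53 to 8.45, 8.44-fold, and was lower in 6 of 6 culture arrays. Hbe1, an embryonic globin, fell from 12.91 to 6.94, 62.5-fold. Cdk1, the kinase that drives entry into mitosis, rose by 1.81 ± 0.23 or 3.50-fold.

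Of 15866 probe sets, 6693 (42.2%) changed: 3128 were higher in culture and 3565 lower. At 2-fold or more 827 changed, 528 higher and 299 lower. The 6 culture values all lay above the 3 tissue values for 3013 probe sets and all below for 3703, where chance gives 2.38% of probe sets for both directions together. With 1 probe set per gene, 2279 genes were higher and 2366 lower. The p-values measure only the spread between these samples, and the 6 culture arrays may hold fewer than 6 independent cultures, as the labels give 3 embryo groups. With a random block for the 2 culture sets and the tissue arrays, 3227 probe sets passed (1879 higher, 1348 lower). That fit allowed for like arrays but still counted arrays, so it is no test with the sets as samples. More were higher than lower also without the dimmest 40% of probe sets (2663 against 1936) or 60% (1894 against 1220) and without MesE11 replicate 1 (2523 against 2518), 2 (2748 against 2739) or 3 (2484 against 2241), in 15 of the 20 choices of 3 culture arrays and in 2 of the 15 ways to average them in pairs. Of the genes named by rule, Pax8, Slc6a3, Stmn2, Slc32a1, Grik2, Gria1, Bdnf, C1qb, Des, Myh3, Rax, Fdft1, Insig1, Ifit3, Mx2, Rpl4 and Rpl27 did not pass with that block.

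The 10 largest rises were those of Col3a1, Lum, Col1a2, Colec12, Cxcl12, Cyp1b1, Col1a1, Ccn2, Serpinf1 and Lgals1. Lum, which encodes the matrix proteoglycan lumican, rose by 5.26 ± 0.13. Cxcl12, a secreted chemokine, rose by 4.02 ± 0.12 (further probe sets by 3.39 ± 0.16 and 2.34 ± 0.20), and Cyp1b1, a cytochrome P450, by 3.83 ± 0.06. Colec12, a scavenger receptor, rose by 4.03 ± 0.18 and Serpinf1, a secreted serpin, by 2.96 ± 0.15. The tissue means of Lum (6.16), Colec12 (5.74) and Serpinf1 (6.62) lay within the 4.80 to 6.68 read by control probe sets for bacterial genes, so these rises are lower bounds if those means are background. Lgals1, galectin 1, rose by 2.71 ± 0.14. Ccn2, connective tissue growth factor, rose by 3.20 ± 0.37, with 11.56 to 12.06 in culture arrays 1 to 3 and 10.41 to 10.63 in arrays 4 to 6. The 10 largest falls were those of Hbe1, Hbb, Crabp2, Cldn5, Hbg1, Hbz, C1qtnf4, Sst, Sncg and Th. Crabp2, which binds retinoic acid in the cell, changed by −4.19 ± 0.12 (18.3-fold lower). C1qtnf4 changed by −3.12 ± 0.60, and its culture values were 7.90 to 8.06 in arrays 1 to 3 and 10.05 to 10.26 in arrays 4 to 6, with which alone it changed by −2.03.

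Of 21 fibroblast and smooth muscle genes measured, 16 were higher and 0 lower, with 16 higher adjusted over the list alone and 15 with the random block (median 1.70, camera adjusted p = 2.9e-10, adjusted p = 0.0756 with an estimated correlation). Col1a2 and Col1a1, the chains of type I collagen, rose by 4.28 ± 0.10 and 3.39 ± 0.13, and a further probe set of Col1a1 rose by 5.60 ± 0.18. Of the members found in smooth muscle, Tagln and Myl9 rose by 2.21 ± 0.51 and 0.80 ± 0.14, while Acta2 and Cnn1 differed by −0.04 ± 0.09 and 0.04 ± 0.08 and did not pass. Both means of Cnn1 lay within the range of the bacterial controls. These 4 genes were picked after their values were seen and were not tested as a group. Camera with an estimated correlation called 0 of the 23 lists, of which 4 had an unadjusted p under 0.05, against 14 with the preset one. Fry, which asks whether the members of a list move on balance one way and compares them with no other genes, called 18.

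Astrocyte genes rose as well, 10 of 16 higher and 0 lower, with 11 higher and 1 lower adjusted over the list alone and 8 higher with the random block (median 0.44, camera adjusted p = 5.4e-05, adjusted p = 0.232 with an estimated correlation). Mlc1, a membrane protein of astrocyte endfeet, rose by 1.89 ± 0.12, and Aqp4, their water channel, by 1.84 ± 0.07. Gja1, connexin 43, rose by 1.66 ± 0.15 and Apoe by 1.46 ± 0.20. A further probe set of Aqp4 fell by 0.42 ± 0.14 (adjusted p = 0.0371) and a further one of Gja1 by 0.31 ± 0.08 (adjusted p = 0.0124), and the tissue mean of Aqp4, 6.32, lay within the range of the bacterial controls. Over the mean of a gene's probe sets the rises were smaller, 0.49 for Aqp4, 0.57 for Gja1 and 0.76 for Apoe. Gfap, the intermediate filament of astrocytes, did not pass, at 8.29 in tissue and 8.37 in culture (difference 0.07 ± 0.08, adjusted p = 0.466). In the oligodendrocyte lineage list, 2 of 12 were higher and 2 lower, or 2 and 1 adjusted over the list alone and also with the random block. Pdgfra, a growth factor receptor also found on mesenchymal cells, rose by 1.81 ± 0.10 and Cldn11 by 1.16 ± 0.23 (0.66 over the mean of its probe sets), whereas the myelin gene Mag fell by 0.37 ± 0.07. That list was not called (adjusted p = 0.691), and its measures differed in sign, with a median of −0.13 and a mean of 0.16, down by camera and up by fry.

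Cell cycle genes rose in 19 of 23 cases with 0 lower, and in 21 adjusted over the list alone and 13 with the random block (median 0.68, camera adjusted p = 7.0e-07, adjusted p = 0.358 with an estimated correlation). Aurkb, a mitotic kinase, rose by 2.50 ± 0.21, Ccnb2, a mitotic cyclin, by 1.78 ± 0.23 and the proliferation marker Mki67 by 1.52 ± 0.27. The median was 0.97 with culture arrays 1 to 3 alone and 0.49 with 4 to 6 alone. Cdk1 read 10.83 to 10.87 in arrays 1 to 3 and 9.88 to 10.20 in arrays 4 to 6, while Aurkb read 10.01 or less in arrays 1 to 3 and 10.61 or more in arrays 4 to 6.

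Neural progenitor genes went both ways: 7 of 17 rose and 5 fell, with the same counts adjusted over the list alone and 5 and 4 with the random block, and the list was not called (median 0.08, adjusted p = 0.565). Id3, an inhibitor of bHLH factors, rose by 2.12 ± 0.16, Prom1 by 2.12 ± 0.10 and Nes, the filament protein of progenitors, by 0.90 ± 0.12. Sox2, a transcription factor of neural stem cells, rose by 0.91 ± 0.18 on its brighter probe set and fell by 0.34 ± 0.12 on the dimmer one; the mean of both was not past the threshold (adjusted p = 0.0932). Hes5, a Notch target, changed by −1.25 ± 0.14 (−0.73 over the mean of its probe sets), and Neurod1, a neurogenic factor, by −0.98 ± 0.09. With centring on ribosomal protein probe sets the median was −0.021. Leaving out the dimmest 60% of probe sets gave a median of 0.88 over the members left, which camera called (adjusted p = 0.0258, adjusted p = 0.390 with an estimated correlation).

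Of the midbrain patterning and floor plate genes, 5 of 11 rose and 2 fell, or 5 and 3 adjusted over the list alone and 4 and 0 with the random block, and the list was not called (median 0.16, adjusted p = 0.103). Otx2, which specifies forebrain and midbrain, rose by 0.87 ± 0.15, Spon1, a floor plate protein, by 0.80 ± 0.12, Shh, the floor plate morphogen, by 0.55 ± 0.07 and Wnt5a by 0.46 ± 0.08. A further probe set of Otx2 fell by 0.25 ± 0.07 (adjusted p = 0.0219), and the mean of both rose by 0.31. Pax8 fell by 0.25 ± 0.07, but not past the threshold without MesE11 replicate 1 (adjusted p = 0.0599) or 3 (0.111) or under quantile normalization (−0.13, adjusted p = 0.142). Foxa2, a floor plate transcription factor, did not pass (0.16 ± 0.19, adjusted p = 0.498). Its values were 9.37 to 9.58 in culture arrays 1 to 3 and 9.99 to 10.17 in arrays 4 to 6, around a tissue mean of 9.61. With arrays 4 to 6 alone Foxa2 rose by 0.49 (adjusted p = 3.7e-04), and the list was called with a median of 0.37 (adjusted p = 0.0177, adjusted p = 0.146 with an estimated correlation).

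Dopaminergic neuron genes fell in 12 of 15 cases and 1 rose, with the same counts adjusted over the list alone, and with the random block 8 fell and 1 rose (median −0.57, camera adjusted p = 3.3e-04, adjusted p = 0.271 with an estimated correlation). Sncg, gamma synuclein, changed by −3.11 ± 0.10 and Th by −3.08 ± 0.14. Ddc, the enzyme after Th in dopamine synthesis, changed by −1.93 ± 0.44 (adjusted p = 0.00655), with culture values of 8.35 to 8.75 in arrays 1 to 3 and 10.16 to 10.19 in arrays 4 to 6. Its dimmer probe set did not pass (−0.21 ± 0.10), the mean of both changed by −1.07, and with arrays 4 to 6 alone Ddc changed by −1.15. Nr4a2, an orphan nuclear receptor needed for these neurons, changed by −1.53 ± 0.25 (a further probe set by −1.02 ± 0.12), and Pitx3, their homeobox factor, by −0.43 ± 0.05 to 6.60, within the range of the bacterial controls. The vesicular transporter Slc18a2 changed by −0.84 ± 0.11 (a further probe set by −1.56 ± 0.19) and the dopamine transporter Slc6a3 by −0.77 ± 0.24 (a further one by −0.25 ± 0.09). The call of Slc6a3 (adjusted p = 0.0290) ended without any 1 tissue array or MesPC replicate 1 (adjusted p from 0.0523 to 0.104). It changed by −1.18 with culture arrays 1 to 3 alone, −0.36 with 4 to 6 alone and −0.51 over the mean of its probe sets. Within these sets alone Slc6a3 passed limma's test (adjusted p = 2.3e-06 and 0.0122). Ret, the GDNF receptor kinase, was the member that rose, by 1.05 ± 0.09, or 0.39 over the mean of its probe sets, of which the others did not pass. The median was −0.78 with culture arrays 1 to 3 alone and −0.41 with 4 to 6 alone.

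**Figure D2:**
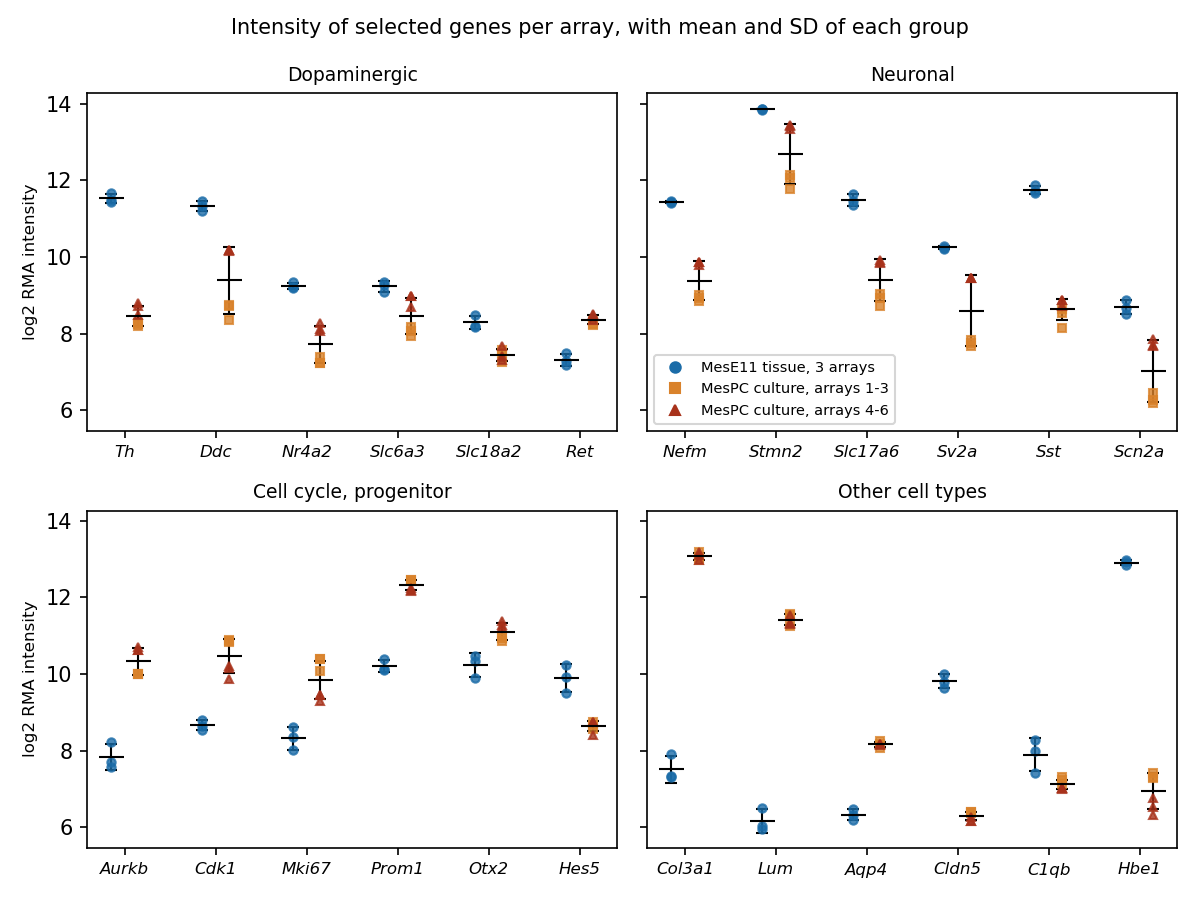
Log2 intensity of named genes, with 1 point per array (circles for tissue, squares for culture arrays 1 to 3, triangles for 4 to 6) and bars for the mean and SD of the 3 tissue and 6 culture arrays. Th falls from a mean of 11.53 in tissue to 8.45 in culture, and Col3a1 rises from 7.51 to 13.07.

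Other neuronal genes were lower too. Of the neuronal cytoskeleton and RNA-binding genes, 8 of 17 fell and 0 rose, and 11 fell adjusted over the list alone and 6 with the random block (median −0.83, camera adjusted p = 7.0e-04, adjusted p = 0.550 with an estimated correlation). The neurofilament genes Nefm and Nefl changed by −2.05 ± 0.25 and −1.59 ± 0.34, and Ina, alpha-internexin, by −1.44 ± 0.42 (a further probe set by −2.11 ± 0.42). Stmn2, a microtubule regulator of growing axons, changed by −1.16 ± 0.39. Ina read 10.82 to 11.19 in culture arrays 1 to 3 and 12.45 to 12.52 in 4 to 6. With arrays 1 to 3 alone Ina changed by −2.20 and Stmn2 by −1.86, and with 4 to 6 alone Ina changed by −0.69, Stmn2 by −0.46 and Nefl by −1.0. The list's median was −1.35 with arrays 1 to 3 alone, where 17 of 17 fell, and −0.34 with arrays 4 to 6 alone, where 11 fell. The calls of Ina and Stmn2 ended without any 1 tissue array, and that of Stmn2 also without MesPC replicate 1 or 3 (adjusted p from 0.0539 to 0.0831 for Ina and from 0.0649 to 0.104 for Stmn2). These losses came with both culture sets in the fit. Within either culture set alone both genes passed limma's test (highest adjusted p = 2.1e-04), though the arrays of a set may not be independent cultures.

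Synaptic vesicle and synapse genes fell in 14 of 25 cases and 0 rose, also adjusted over the list alone, and in 9 with the random block (median −0.42, camera adjusted p = 0.0044, adjusted p = 0.550 with an estimated correlation). Sv2a, a vesicle glycoprotein, changed by −1.66 ± 0.47, Cplx1, a complexin of vesicle release, by −1.52 ± 0.25 (a further probe set by −0.40 ± 0.07), Sncb, beta synuclein, by −1.44 ± 0.48 (a further one by −0.65 ± 0.14) and the SNARE gene Stx1a by −1.15 ± 0.38. The median was −0.72 with culture arrays 1 to 3 alone and −0.24 with 4 to 6 alone. Without any 1 tissue array Sv2a, Sncb and Stx1a no longer passed, and Sncb and Stx1a did not without any 1 of MesPC replicates 1 to 3 (highest adjusted p 0.0593, 0.0950 and 0.0918). These 3 genes changed by −2.50, −2.30 and −1.83 with arrays 1 to 3 alone and by −0.81, −0.58 and −0.48 with 4 to 6 alone, and the mean of the Cplx1 probe sets changed by −0.96. Within either culture set alone these 3 genes passed limma's test (highest adjusted p = 4.2e-04). Voltage-gated ion channel genes fell in 13 of 24 cases, 15 adjusted over the list alone and 8 with the random block, with 0 higher (median −0.36, camera adjusted p = 7.4e-04, adjusted p = 0.271 with an estimated correlation). Of these 13, 3 had means below the highest bacterial control in both groups. The sodium channel genes Scn2a, Scn3b and Scn1a changed by −1.66 ± 0.41, −1.60 ± 0.43 and −1.17 ± 0.32, and the potassium channel gene Kcnd2 by −1.07 ± 0.18. Scn2a read 6.18 to 6.45 in culture arrays 1 to 3 and 7.68 to 7.86 in 4 to 6, and Scn1a 6.21 to 6.27 in arrays 1 to 3, where both lay within the range of the bacterial controls. With arrays 4 to 6 alone Scn2a, Scn3b and Scn1a changed by −0.93, −0.84 and −0.60 and passed limma's test (highest adjusted p = 1.3e-04). Without MesE11 replicate 1 the adjusted p was 0.0523 for Scn3b and 0.0585 for Scn1a, and without MesE11 replicate 3 it was 0.0511 and 0.0526.

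GABA and glutamate transmission genes fell in 9 of 18 cases and 1 rose, or 11 and 1 adjusted over the list alone and 4 and 0 with the random block (median −0.31, camera adjusted p = 0.0050, adjusted p = 0.222 with an estimated correlation). Slc17a6, the vesicular glutamate transporter VGLUT2, changed by −2.09 ± 0.28. The vesicular GABA transporter Slc32a1 changed by −1.25 ± 0.44 and the glutamate receptor genes Grik2 and Gria2 by −0.81 ± 0.27 and −0.69 ± 0.12. A further probe set of Gria2 did not pass (−0.55 ± 0.28, adjusted p = 0.138). Gria1 rose by 0.18 ± 0.06 (adjusted p = 0.0418), a call that ended under median centring (adjusted p = 0.0808), with centring on ribosomal protein probe sets (0.077, adjusted p = 0.514) and without any 1 array other than MesPC replicates 4 and 5; under quantile normalization the difference was 0.30. The calls of Slc32a1 and Grik2 ended without any 1 tissue array or any 1 of MesPC replicates 1 to 3 (adjusted p from 0.0532 to 0.127 and from 0.0506 to 0.105; from 0.0528 to 0.135 for Gria1). With arrays 1 to 3 alone Slc32a1 and Grik2 changed by −1.99 and −1.29, and with 4 to 6 alone by −0.52 and −0.33. Within either culture set alone both passed limma's test (highest adjusted p = 0.0060). Serotonergic and cholinergic genes fell in 9 of 10 cases, 10 adjusted over the list alone and 6 with the random block, with 0 higher (median −0.41, camera adjusted p = 1.8e-04, adjusted p = 0.0756 with an estimated correlation). Of these 9, 2 had means below the highest bacterial control in both groups. The serotonin transporter Slc6a4 changed by −1.49 ± 0.21 and Gata3, a factor of serotonergic and GABAergic neurons, by −0.87 ± 0.23 (−0.48 with arrays 4 to 6 alone). The choline transporter Slc5a7 and the vesicular acetylcholine transporter Slc18a3 changed by −0.83 ± 0.07 and −0.61 ± 0.06.

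Neuropeptide and neurotrophin genes fell in 13 of 18 cases, 16 adjusted over the list alone and 7 with the random block, with 0 higher (median −0.52, camera adjusted p = 9.8e-06, adjusted p = 0.0756 with an estimated correlation). Of these 13, 3 had means below the highest bacterial control (6.68) in both groups and 2 in 1 group. Sst, somatostatin, changed by −3.11 ± 0.15 from a tissue mean of 11.75. Tac1, the precursor of substance P, changed by −1.99 ± 0.13, Nrn1, neuritin, by −1.73 ± 0.13 and Npy, neuropeptide Y, by −1.71 ± 0.17. Bdnf, a neurotrophin, changed by −0.29 ± 0.07 (adjusted p = 0.0090), and not past the threshold after quantile normalization (−0.16, adjusted p = 0.140).

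**Figure D3:**
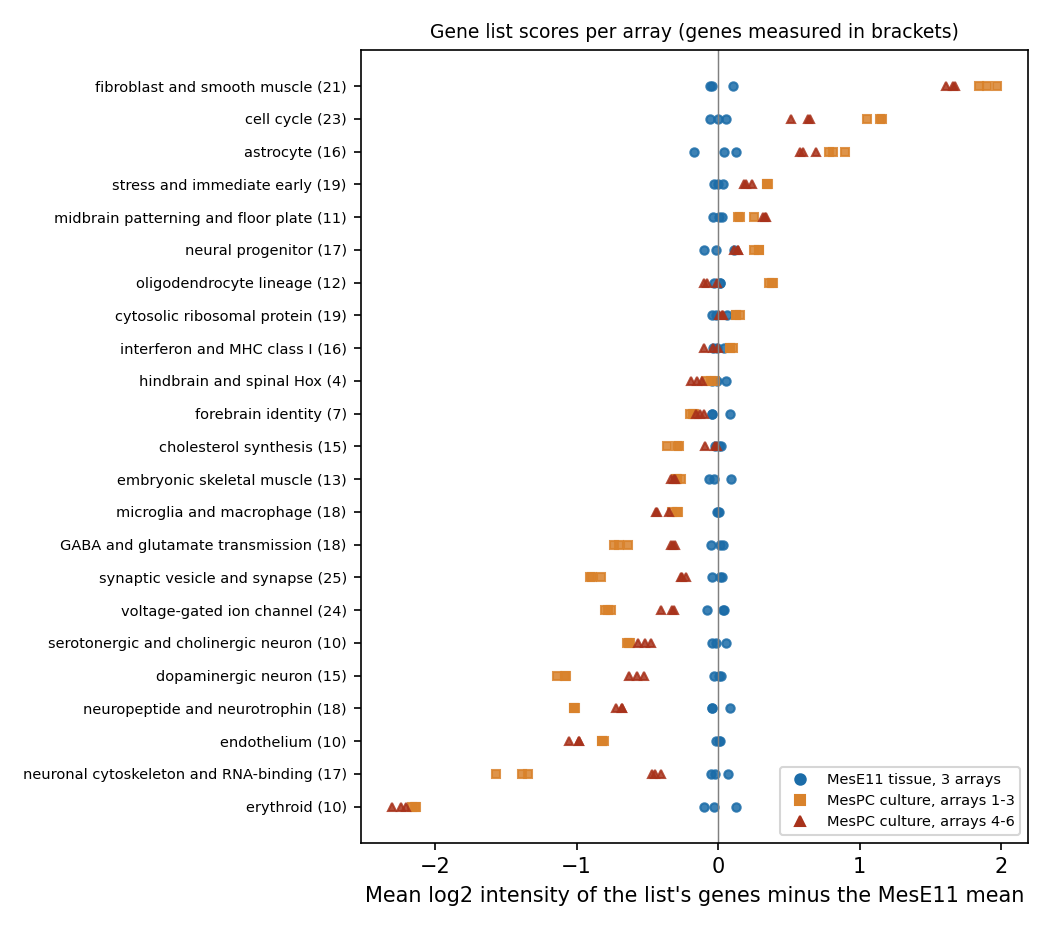
Mean log2 difference of the members of each gene list from the tissue mean (horizontal axis), with 1 point per array and the number of genes measured in brackets. The erythroid list lies at −2.13 or lower in all 6 culture arrays, and the neuronal cytoskeleton list lies between −1.57 and −1.34 in arrays 1 to 3 and between −0.47 and −0.41 in arrays 4 to 6.

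Blood, vessel and immune cell genes were lower in culture. Erythroid genes fell in 9 of 10 cases and 0 rose, also adjusted over the list alone, and in 6 with the random block (median −1.46, camera adjusted p = 1.1e-06, adjusted p = 0.0756 with an estimated correlation). The globin genes Hbe1, Hbg1 and Hbz changed by −5.97 ± 0.24, −3.32 ± 0.11 and −3.16 ± 0.11. Hbb changed by −5.45 ± 0.11, on a probe set of a type that can also bind transcripts of related genes. Endothelium genes fell in 7 of 10 cases and 0 rose, also adjusted over the list alone and with the random block (median −0.71, camera adjusted p = 2.2e-05, adjusted p = 0.222 with an estimated correlation). Cldn5, a tight junction gene of brain vessels, changed by −3.52 ± 0.09, Kdr, the VEGF receptor, by −1.51 ± 0.12, Tie1 by −0.87 ± 0.09 and Vwf by −0.81 ± 0.07. Microglia and macrophage genes fell in 10 of 18 cases and 0 rose, also adjusted over the list alone, and in 6 with the random block (median −0.29, camera adjusted p = 1.8e-04, adjusted p = 0.222 with an estimated correlation). The complement genes C1qb, C1qa and C1qc changed by −0.78 ± 0.16, −0.74 ± 0.08 and −0.61 ± 0.08, and the protease gene Ctss by −0.75 ± 0.08. The culture means of Hbg1 (5.99), Cldn5 (6.29), C1qc (6.62) and Vwf (6.68), and the means of arrays 4 to 6 for Hbe1 (6.53), Hbz (6.65) and Tie1 (6.63), lay within the range of the bacterial controls, so these falls are lower bounds if those means are background. Without the dimmest 40% of probe sets the microglia list was not called (median −0.13, adjusted p = 0.148).

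Of the embryonic skeletal muscle genes, 5 of 13 fell and 0 rose, or 8 adjusted over the list alone and 2 with the random block (median −0.22, camera adjusted p = 0.0147, adjusted p = 0.358 with an estimated correlation). Acta1, skeletal actin, changed by −1.59 ± 0.20, Tnnc1 by −0.46 ± 0.07, and Des and Myh3 both by −0.22 ± 0.07. The list's call ended after quantile normalization (adjusted p = 0.131) and without MesE11 replicate 3 (adjusted p = 0.0528). It also ended with culture arrays 1 to 3 alone (adjusted p = 0.0816) and over the arrays numbered 1 to 3 with the replicate number as a block (0.0838). Des no longer passed without MesE11 replicate 1 or 3 or any 1 of MesPC replicates 4 to 6 (adjusted p from 0.0589 to 0.162, and a difference of −0.13 without MesE11 replicate 3). Nor did it under quantile normalization (adjusted p = 0.0739), with the replicate block (0.125) or with culture arrays 1 to 3 alone (0.127). Myh3 did not pass without MesE11 replicate 2 (0.0573) or 3 (0.111), under quantile normalization (−0.13, adjusted p = 0.0993) or with the replicate block (0.0547). Stress and immediate early genes rose in 7 of 19 cases and 0 fell, also adjusted over the list alone, and in 6 with the random block, but the list was not called (median 0.04, adjusted p = 0.0857). Asns, asparagine synthetase, rose by 1.34 ± 0.08, Hmox1, heme oxygenase 1, by 1.28 ± 0.09, Egr1 by 1.04 ± 0.25 (0.61 with arrays 4 to 6 alone) and Gadd45a by 1.01 ± 0.08. The sign of that list's median turned with centring on ribosomal protein probe sets (−0.064), and camera called the list after quantile normalization (adjusted p = 0.0294, adjusted p = 0.403 with an estimated correlation). Camera also called it without the dimmest 40% of probe sets (adjusted p = 0.0148), with array weights (0.0457), with the replicate block (0.0301), with culture arrays 1 to 3 alone (0.0374) and over the mean of a gene's probe sets (0.0146). None of these calls held with an estimated correlation.

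Cholesterol synthesis genes fell in 6 of 15 cases and 1 rose, also adjusted over the list alone, or 3 and 0 with the random block, and the list was not called (median −0.12, adjusted p = 0.221). Mvd changed by −0.84 ± 0.13, Idi1 by −0.71 ± 0.14 (−0.46 with arrays 4 to 6 alone), Pmvk by −0.51 ± 0.10 and Fdft1 by −0.39 ± 0.14, all enzymes of the pathway. Insig1, which retains the regulator of the pathway in the endoplasmic reticulum, rose by 0.35 ± 0.07. Fdft1 no longer passed without any 1 tissue array or any 1 of MesPC replicates 1 to 3 (adjusted p from 0.0644 to 0.138). It changed by −0.63 with arrays 1 to 3 alone and differed by −0.16 with 4 to 6 alone (adjusted p = 0.0808). With culture arrays 1 to 3 alone the list was called (median −0.29, adjusted p = 0.0186, adjusted p = 0.199 with an estimated correlation). In the interferon and MHC class I list 2 of 16 rose and 3 fell, also adjusted over the list alone, or 1 and 1 with the random block, with no call (adjusted p = 0.926), a median of −0.04, a mean of 0.02, and camera down where fry was up. B2m, the light chain of MHC class I, rose by 1.33 ± 0.09 and Mx2 by 0.37 ± 0.07, while Psmb8 fell by 0.50 ± 0.09 and Ifit3 by 0.18 ± 0.05, the latter not past the threshold without MesE11 replicate 1 (adjusted p = 0.0579) or 3 (0.0610) or under quantile normalization (−0.061, adjusted p = 0.385), and −0.28 with centring on ribosomal protein probe sets. Of the forebrain identity genes 1 of 7 fell, Rax by 0.18 ± 0.06, and 0 adjusted over the list alone or with the random block (median −0.18, adjusted p = 0.513); Rax did not pass without any 1 tissue array (adjusted p from 0.0507 to 0.0976), under quantile normalization (−0.13, adjusted p = 0.0578) or with culture arrays 1 to 3 alone (−0.12, adjusted p = 0.113), and was −0.29 with centring on ribosomal protein probe sets. None of the 4 hindbrain and spinal Hox list genes passed limma's test over all probe sets, adjusted over the list alone or with the random block, and 1 was lower at an unadjusted p under 0.05 (median −0.12, adjusted p = 0.435). Cytosolic ribosomal protein genes rose in 2 of 19 cases, Rpl4 by 0.25 ± 0.07 and Rpl27 by 0.24 ± 0.07, and in 0 adjusted over the list alone or with the random block, with 5 higher at an unadjusted p under 0.05 (median 0.08, adjusted p = 0.103). Both calls ended with centring on these probe sets (0.14, adjusted p = 0.101, and 0.13, adjusted p = 0.188) and without MesE11 replicate 1 (adjusted p 0.0727 for Rpl4 and 0.0695 for Rpl27, the latter at 0.15), and that of Rpl4 without replicate 3 (0.0754).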

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

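The tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays. In a search of 133 groups of 6 culture values, 5 held 1 array far from the other 5, and chance alone gives about 1 in 20. Gria1 read 7.13 in MesPC replicate 4, against 6.89 to 6.97 in the other culture arrays. Slc5a7 read 5.36 in MesPC replicate 1, against 5.15 to 5.22. Mlc1 read 10.58 in MesPC replicate 6, against 10.76 to 10.80. Myh3 read 6.99 in MesPC replicate 4, against 7.13 to 7.20. The 3′ minus 5′ difference of the GAPDH control probe sets was 0.729 in MesPC replicate 4, against 0.558 to 0.610 in the others.

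Neuronal genes were lower and cell cycle genes higher in culture. Chance can be excluded for the counts only if the 9 arrays are independent. Of the 84 splits into 3 and 6, only the real one reached 6693 changed probe sets, the highest other being 3335. It alone also reached 827 at 2-fold or more, the highest other being 512. However, 81 splits gave 0, and only the 3 that kept a set of like arrays whole gave any, the real one included. With these sets as units the splits are thus too few. A swap of the group labels was excluded by the erythroid list, whose highest mean difference in a culture array was −2.13. A single scaling shift was excluded because the neuronal cytoskeleton median stayed at −0.93 after centring on ribosomal protein probe sets, and a lower share of neurons that raised every other cell type alike because the endothelium median was −0.71 while the fibroblast median was 1.70. An uneven change in the shares of the cell types was not tested and stayed open. A difference in processing or hybridization stayed open, since the BioD minus BioB control difference was 2.42 to 2.46 in tissue and 2.73 to 3.14 in culture and the GAPDH 3′ minus 5′ difference lay below every tissue array in 5 of 6 culture arrays; growth in culture, age and time in vitro, which differ between the groups together, and changes within the cell types that rose stayed open and untested.

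Culture arrays 1 to 3 and 4 to 6 stood apart. The highest counts among the other splits, 3335 and 512, both came from setting culture arrays 1 to 3 against the rest, which points to a structure of the samples. Tissue RNA mixed into arrays 4 to 6, which were nearer to tissue, was excluded by Hbb: its highest value there was 8.49, below the lowest of arrays 1 to 3, 8.54. A difference between hybridization batches stayed open, since the BioD minus BioB control difference parted the sets by a gap of 0.035, narrower than the range of 0.213 within a set. The actin 3′ minus 5′ difference also parted them, at 0.350 to 0.490 in arrays 1 to 3 and 0.536 to 0.669 in arrays 4 to 6, while that of GAPDH overlapped. A difference in processing therefore stayed open too. The labels give no group for these sets, so no biological explanation was tested.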

How the results depend on the processing

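The random block for the culture sets, the dopaminergic list without Th and Sncg, the estimated correlation under the alternatives that gained a list, each culture set alone and the estimated correlation within each set were chosen after the data were seen; the other alternatives were planned. No list or named gene past the threshold turned direction, but the medians of the neural progenitor, stress, interferon, oligodendrocyte and ribosomal lists and the differences of Gfap and Foxa2, none of them called, turned sign under some alternatives. The balance of more lower than higher probe sets turned without the dimmest 40% (2663 higher, 1936 lower) or 60%, with the random block, and without MesE11 replicate 1 (2523 higher, 2518 lower), 2 (2748, 2739) or 3 (2484, 2241), and in 15 of the 20 choices of 3 culture arrays and 2 of the 15 pairings. Of 610 list results under alternatives, 565 stayed on their side of the threshold, 25 passed where they had not and 20 no longer passed; for named genes the counts were 1939, 1 and 113. Of 100 named genes past the threshold, 24 lost the call under at least 1 alternative, 19 of them with 1 array left out and 17 with the random block. Fewer lost it within 1 culture set alone, 2 with arrays 1 to 3 and 5 with arrays 4 to 6. The causes were not tested except where fewer probe sets or arrays show them.

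Without the dimmest 40% of probe sets, where fewer are tested, 1936 were lower and the higher share of changed probe sets went from 46.7% to 57.9%; the microglia median was −0.13 and the stress median 0.51. Without the dimmest 60%, 3114 changed (1894 higher, 1220 lower, 60.8% higher), 471 at 2-fold or more (326 and 145), and the neural progenitor median was 0.88. Centring on ribosomal protein probe sets moved the median of all genes by −0.11, so that 5605 were lower and 28.8% of the changed higher; the changes are relative to this shift, and the median signs of the neural progenitor, stress and ribosomal lists turned without a call. Median centring gave 38.1% higher. Quantile normalization gave medians of 0.20 (midbrain patterning), −0.11 (embryonic skeletal muscle), −0.18 (cholesterol synthesis) and 0.067 (stress). Array weights gave 504 lower at 2-fold or more and medians of 0.020 (stress) and 0.11 (ribosomal protein). The mean of a gene's probe sets gave a stress median of 0.11. Treat against 2-fold called 219, 179 higher and 40 lower, as its stricter hypothesis requires.

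Leaving out 1 array, the count of lower probe sets ran from 2241, without MesE11 replicate 3, to 3458. The embryonic skeletal muscle median ran from −0.23 to −0.13 and lost its call without MesE11 replicate 3; the ribosomal protein median ran from 0.042 to 0.099 and was called without MesE11 replicate 2. All changed probe sets ran from 4725 to 6557. The arrays numbered 1 to 3, with the replicate number as a block or without it, and culture arrays 1 to 3 alone gave 1329 at 2-fold or more, 624 of them lower. There the embryonic skeletal muscle list (median −0.16) lost its call, while the cholesterol synthesis (−0.29) and stress (0.0014) lists gained one. Unblocked, the ribosomal protein list (0.14) gained a call too. The block moved the count of changed probe sets from 7879 to 7521. Deviations from the group means of like-numbered arrays had r of 0.084, −0.119 and −0.111. These values gave no sign of pairing by number. Only arrays numbered 1 to 3 were checked, and only in that match, so a shared origin of tissue and culture samples was not excluded. Over the 20 choices of 3 culture arrays the lowest counts were 3976 changed, 1802 lower and 148 lower at 2-fold or more, and the highest at 2-fold were 1329 and 624 lower; the extreme medians that changed a call were 0.37 (midbrain patterning), −0.29 (cholesterol synthesis) and 0.14 (ribosomal protein). Culture arrays 4 to 6 alone gave 148 lower at 2-fold or more and a midbrain patterning median of 0.37. The 15 ways to average culture arrays in pairs gave 5556 to 8580 changed. With the random block, where the correlation within a set was taken as 0.447 for every probe set, 3227 changed, 1879 higher and 1348 lower (58.2% higher). That correlation was also applied among the tissue arrays, so part of the drop may come from them.

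Camera with an estimated correlation called 0 lists, also with culture arrays 1 to 3 alone (0) and 4 to 6 alone (0). Even the erythroid list, with 9 of 10 genes lower, reached only adjusted p = 0.0756 in that test, and 0.089 and 0.118 within these sets. With so few arrays the test had little power, so a missing call does not show that a list held steady. The medians of the 14 lists that lost their call were unchanged by construction: −0.57 (dopaminergic), 0.68 (cell cycle), −0.83 (neuronal cytoskeleton), −0.42 (synaptic), −0.36 (ion channel), −0.31 (GABA and glutamate), −0.41 (serotonergic and cholinergic), −0.52 (neuropeptide), 0.44 (astrocyte), −0.29 (microglia), 1.70 (fibroblast), −0.71 (endothelium), −1.46 (erythroid) and −0.22 (embryonic skeletal muscle). The lists that gained a call under an alternative also lost it with an estimated correlation (lowest adjusted p = 0.135). Fry also called midbrain patterning (0.16), neural progenitor (0.084), forebrain (−0.18) and stress (0.041). Signal near the background limits dim genes: the 27 control probe sets for Bacillus subtilis genes read 4.80 to 6.68, and Rax, Slc5a7, Pax8 and Ifit3 had means below that limit in both groups. The tissue means of Lum, Colec12, Serpinf1 and Aqp4 and the culture means of Cldn5, Hbg1, Mag, C1qc, Vwf, Tnnc1, Pitx3 and Bdnf also lay below it, so that the sizes of these differences are lower bounds if those means are background.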

Other observations

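The symbol families and the tests of explanations in this part were chosen after the data were seen. Genes were also grouped by the root of their symbol, and the 176 families with 8 or more members were tested with camera; 5 were called with the preset correlation and 0 with an estimated one (adjusted p = 0.854 with an estimated correlation), of which 3 had an unadjusted p under 0.05. Of 29 collagen genes 16 rose and 4 fell (median 0.75, adjusted p = 1.2e-04), 3 of these 20 with means below the highest bacterial control (6.68) in both groups and 1 in 1 group. Beyond the fibrillar chains, the basement membrane genes Col4a1 and Col4a2 rose by 2.19 ± 0.08 and 2.11 ± 0.06, and Col6a3 by 2.43 ± 0.11. Col2a1, a fibrillar collagen of cartilage and early epithelia, changed by −2.28 ± 0.18. Annexin genes rose in 6 of 9 cases (median 1.22, adjusted p = 0.0121), with Anxa11 higher by 2.30 ± 0.14 and Anxa1 by 2.11 ± 0.10.

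Of 8 Tmed genes, which encode cargo receptors between endoplasmic reticulum and Golgi, 7 rose and 0 fell (median 0.43, adjusted p = 0.0099), such as Tmed1 by 0.85 ± 0.14 and Tmed10 by 0.84 ± 0.09. The Sec family, which joins coat and translocon genes with others that share the root, rose in 13 of 21 cases and fell in 1 (median 0.26, adjusted p = 0.0099); Sec24d, a coat protein of vesicles leaving the endoplasmic reticulum, rose by 1.77 ± 0.08. Genes with the root Fgf, grouped by symbol and not by function, fell in 10 of 22 cases and 0 rose (median −0.20, adjusted p = 0.0244), with Fgf13 at −1.17 ± 0.36 and Fgf9 at −0.50 ± 0.10. Of these 10, 2 had means below 6.68 in both groups and 3 in culture, as had 8 and 5 of all 22 in both or 1 group. Some families that were not called had medians as low, such as Tas (−0.25, 6 of 10 lower) and Serpina (−0.24, 6 of 11 lower). A fall of this size was thus not particular to the Fgf root. The signs of the medians of the 5 called families held under quantile normalization, median centring and ribosomal centring. The median of the Fgf family shrank to −0.091 under quantile normalization and that of the Sec family to 0.16 under ribosomal centring. The genes named from these families were picked after their values were seen.

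Th and Sncg fell further than most neuronal genes, and a loss specific to dopaminergic genes was tested as a hypothesis. It needed the dopaminergic list to lie below the neuronal cytoskeleton list in every culture array; this held in 3 of 6, with differences of −0.16, −0.08 and −0.17 in arrays 4 to 6 and 0.31, 0.43 and 0.26 in arrays 1 to 3. The result was negative against the cytoskeleton list. The dopaminergic list also lay below the neuropeptide list in 3 of 6 arrays, and below the synaptic, ion channel, GABA and glutamate, and serotonergic lists in 6 of 6. Much of this rested on Th and Sncg, the genes that prompted the test: without them the dopaminergic list lay below these 6 lists in 0 (cytoskeleton, synaptic, neuropeptide), 2 (ion channel) or 3 (GABA and glutamate, serotonergic) of 6 arrays. The other lists kept their largest falls, such as that of Sst in the neuropeptide list. Taking the largest falls from the dopaminergic list alone pushed the comparison without Th and Sncg away from a larger dopaminergic fall. It therefore cannot decide the question.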
